A study of Homo sapiens with 26 samples.

How the data were processed

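RNA of THP-1 and RPMI-8226 cells was measured in 26 libraries, 13 per line, after 4 h with PBS or with R848, ADU-S100, UDSP-Hep or ADP-Hep at 0.1, 1 or 10 µM, with 1 library per condition. Per the labels' protocols, the cells grew in RPMI 1640 with fetal bovine serum, and libraries were made with mRNA capture beads and a Vazyme kit for Illumina sequencing. The authors deposited a table of raw counts per gene for all libraries, and the labels name each library's column in it. The submitters' processing notes name FastQC, Trim Galore, STAR, featureCounts, RSEM and DESeq2 without role, order or version, and the builds hg38 and mm10. The annotation release, the strand setting, the filters and whether reads or fragments were counted are not given in the sources used here. The deposited values were whole counts of 0 or more, and 58274 of the 62710 gene identifiers were found in GENCODE 29 for hg38, from which positions are given. Gene symbols are those of the table. The table had 62757 entries, with 47 identifiers present in 2 entries, which were summed. Of these pairs 13 were equal, all at 0, and 34 were unequal with 1 entry at 0. Entries that sum to 0 made up 38.7%, among them all 37 mitochondrially encoded genes. With the counting strand unknown, values of overlapping genes such as ALPK1 and TIFA, and of near-identical genes such as CCL4 and CCL4L2 or HSPA1A and HSPA1B, may hold each other's reads.

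Library totals were 34271852 to 48921493 counts, with 14536 to 17349 genes at 10 counts or more, and the 10 most abundant genes took 5.55 to 7.82% of counts. A count of 0 allows up to 0.0613 to 0.0875 CPM, taking 3 counts as the floor in each library. No 2 of the 156 library pairs within a line were identical. CPM values are scaled by trimmed mean of M-values (TMM) factors, which ran from 0.935 to 1.07, within a line for responses and over all 26 libraries for the receptor comparison.

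Genes with at least 10 counts in 2 or more libraries of a line and 30 in total were tested, which left 19207 genes in THP-1 and 17559 in RPMI-8226. Each line was fitted with edgeR 4.0.16 quasi-likelihood models (robust, TMM) in R 4.3.3, with a mean for each agent and PBS and a slope on log10 dose, centred at 1 µM, for each of the 4 agents. That gives 9 coefficients for 13 libraries and 4 residual degrees of freedom, so error is the departure from a straight dose line pooled over agents. The common coefficient of biological variation was 0.113 in THP-1 and 0.0880 in RPMI-8226. Each agent was compared with PBS (the mean of its doses against the 1 PBS library of the line), along dose (change per 10-fold dose), and UDSP-Hep with ADP-Hep (mean and slope). A joint fit of 26 libraries with 18 coefficients tested differences of responses between the lines on 21878 genes, of which 15125 were counted in both, and the receptor comparison used the 13 conditions as blocks with 12 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each contrast at 0.05, and all tests are two-sided. Errors of log2 changes are derived from the quasi-likelihood F statistic. Folds are given for genes with more than 3 counts in PBS. A gene with 0 counts in PBS is given as a lower bound against the 3-count floor. Single libraries were also set against PBS with a prior count of 2, counting genes at 2-fold or more with at least 5 CPM in either library.

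A set of 18 gene lists of 12 to 42 members was tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. The lists were NF-kB pathway targets and feedback, inflammatory cytokines and chemokines, type I interferon-stimulated genes, interferon genes, immediate early and AP-1 genes, agonist receptors and signalling proteins, feedback inhibitors of cytokine and Toll-like receptor signalling, p53 targets and apoptosis, unfolded protein and integrated stress response, cell cycle and DNA replication, MHC class I presentation, sterol biosynthesis and uptake, glycolysis and hypoxia, NRF2 targets and metallothioneins, markers of monocytes and macrophages, of B and plasma cells and of T and NK cells, and mitochondrially encoded transcripts. A further number beside a list count in parentheses is the count adjusted over the list alone. Interferon genes had too few tested members for a set test. Named genes followed a rule: for each list discussed the 2 to 4 members with the largest change, and outside the lists from the 10 largest rises and 5 largest falls past the threshold with a mean of at least 1 CPM and the same sign at all 3 doses (for slopes, the same direction at both dose steps). For UDSP-Hep against ADP-Hep they came from the 10 largest differences. Genes known only by a clone or antisense name were counted and not named, and 2 further genes are not reported here. Groups, contrasts, lists, the naming rule and most alternatives were chosen before the data were examined.

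The models were tested on simulated counts with 200 changed genes. Changes were placed in 1 contrast at a time, equal at all doses or along a straight dose line, with no other effect of an agent. Recovery and false calls for curved dose responses, or with many genes changed by several agents, were not simulated. In THP-1, edgeR recovered 76.0% of changes of log2 1 and 94.0% of log2 2 for ADP-Hep against PBS, with 6.59% false calls, and 74.0% and 90.0% of slopes of log2 0.5 and 1 per 10-fold dose with 14.1% false calls, above the nominal rate. In RPMI-8226 it recovered 79.0% and 99.0% against PBS (7.77% false) and 71.0% and 95.0% of slopes (8.29% false). Alternatives were DESeq2 1.42.0, limma-voom, relative log expression scaling, other filters, agent means without slopes, linear dose, the joint fit, leaving out each library of an agent, other prior counts and CPM floors, and several chosen later. No library was left out of the main comparisons.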

Results

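The human cell lines THP-1, a monocyte line, and RPMI-8226, a B lymphocyte line derived from a myeloma, were profiled by poly(A) RNA sequencing after 4 h with innate immune agonists. The series asks how the expression profiles induced by different innate pathways compare in the lines. Each line was treated with ADP-Hep or UDSP-Hep, named in the labels as agonists of the cytosolic kinase ALPK1, with R848, an agonist of Toll-like receptors 7 and 8, or with ADU-S100, an agonist of STING, at 0.1, 1 and 10 µM, beside PBS. Each of the 13 conditions of a line was 1 library, 26 in all, so no condition was replicated. Library totals were 34271852 to 48405849 counts in THP-1 and 35659626 to 48921493 in RPMI-8226. Without replicates, the tests take the departure of each agent's 3 doses from a straight line in log10 dose as error, and nothing in the labels says whether the libraries came from separate cultures. Values after ± beside log2 changes are standard errors from edgeR, and intervals and floors cover counting error only unless named as fitted.

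Both lines carried the marker genes of their type. The median member of the monocyte and macrophage marker list lay at 99.0 CPM in THP-1 and at 0.0562 CPM in RPMI-8226, and 24 against 7 of its 28 members reached 1 CPM. The B and plasma cell list lay at 0.124 CPM in THP-1 and 11.6 CPM in RPMI-8226, with 6 and 17 of 26 members at 1 CPM or more. The median marker of T and NK cells was low in both, at 0.0199 and 0.0124 CPM, although 4 of the 20 members in THP-1 and 2 in RPMI-8226 reached 1 CPM.

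Receptor genes of the agonists differed in level between the lines. ALPK1 (chromosome 4, 112285509 to 112442620, plus strand, hg38) was at 21.1 ± 3.69 CPM in THP-1 and 7.84 ± 1.65 CPM in RPMI-8226 (SD, n = 13 libraries each). That was 2.70-fold higher in THP-1, in 13 of 13 pairs of matched condition (edgeR adjusted p = 5e-11). TIFA, the adaptor that ALPK1 phosphorylates, overlaps ALPK1 on the other strand (112274542 to 112285903). It was 2.05-fold higher in RPMI-8226, at 65.0 ± 8.23 against 35.8 ± 19.4 CPM, also in 13 of 13 pairs (adjusted p = 1.4e-05). STING1 was 10.9-fold higher in THP-1, at 109 ± 28.4 against 9.81 ± 1.86 CPM. CGAS, the DNA sensor upstream of STING1, was 1.37-fold higher in RPMI-8226. TLR7 was 2.02-fold higher in RPMI-8226 (adjusted p = 0.0045), although THP-1 had the higher value in 2 pairs. TLR8 was at 2.99 ± 2.01 CPM in THP-1 and had 6 counts over all RPMI-8226 libraries. These means and SDs include the treated libraries, and several of these genes changed with treatment. The 13 pairs are different conditions and not replicates of 1 condition. The p-values therefore measure how constant a difference was over conditions, and not variation between independent cultures of a line. In the PBS libraries alone ALPK1 stood at 22.6 CPM in THP-1 and 11.8 CPM in RPMI-8226, and TIFA at 23.4 and 57.4 CPM. There STING1 stood at 138 and 10.3 CPM, TLR7 at 1.87 and 3.30 CPM, and TLR8 at 0.757 and 0 CPM. In total 23 of the 26 members of the receptor and signalling list differed (23 adjusted over the list alone), 12 higher in THP-1 and 11 in RPMI-8226, while IRF3, TAB1 and IKBKG did not pass. Most genes differed between these lines, 18085 of 21878 tested, so a difference in this list is not specific to it.

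**Figure D1:**
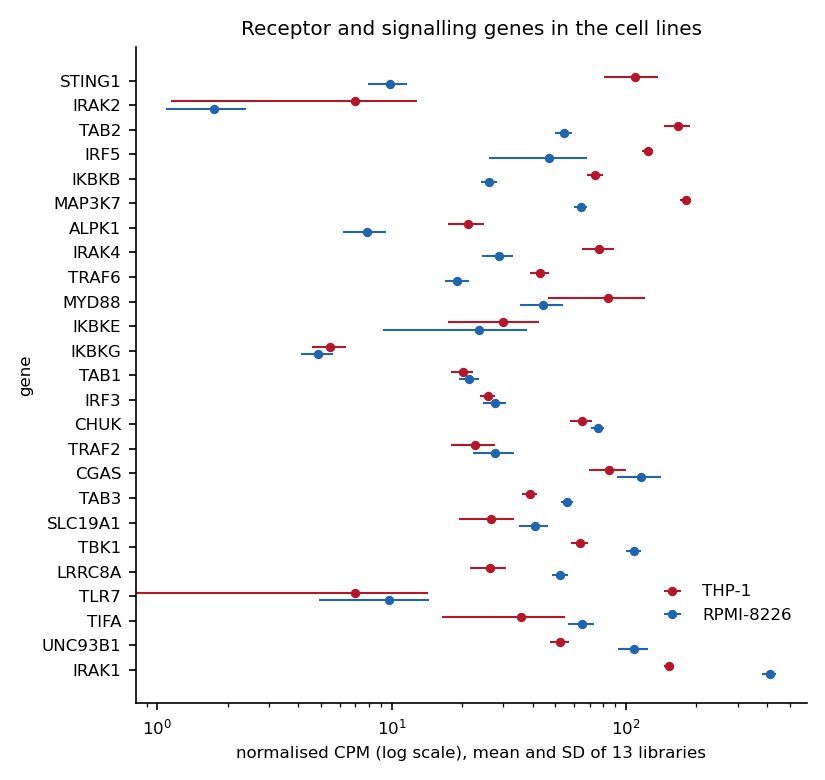
Each point is the mean normalised CPM (log scale) of a receptor or signalling gene over the 13 libraries of a line, treated and PBS, and each bar its SD, with genes that had fewer than 100 counts over the RPMI-8226 libraries left out. ALPK1 stands at 21.1 CPM in THP-1 and 7.84 in RPMI-8226, STING1 at 109 and 9.81, and TIFA at 35.8 and 65.0.

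The agents differed in how the number of responding genes grew with dose. In THP-1, UDSP-Hep moved 715 genes by 2-fold or more against PBS at 0.1 µM, 752 at 1 µM and 765 at 10 µM, whereas ADP-Hep moved 7, 255 and 939. R848 moved 9, 7 and 153, and ADU-S100 111, 138 and 197. In RPMI-8226 the numbers were 372, 349 and 333 with UDSP-Hep and 11, 200 and 486 with ADP-Hep. There R848 moved 15, 24 and 106 genes and ADU-S100 169, 258 and 505. These counts set 1 library against 1, carry no test and depend on the floor of 5 CPM. With floors of 1 and 20 CPM, THP-1 had 1440 and 399 such genes at 0.1 µM UDSP-Hep and 263 and 0 at 0.1 µM ADP-Hep, and all 24 counts moved by over 1.5 times.

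**Figure D2:**
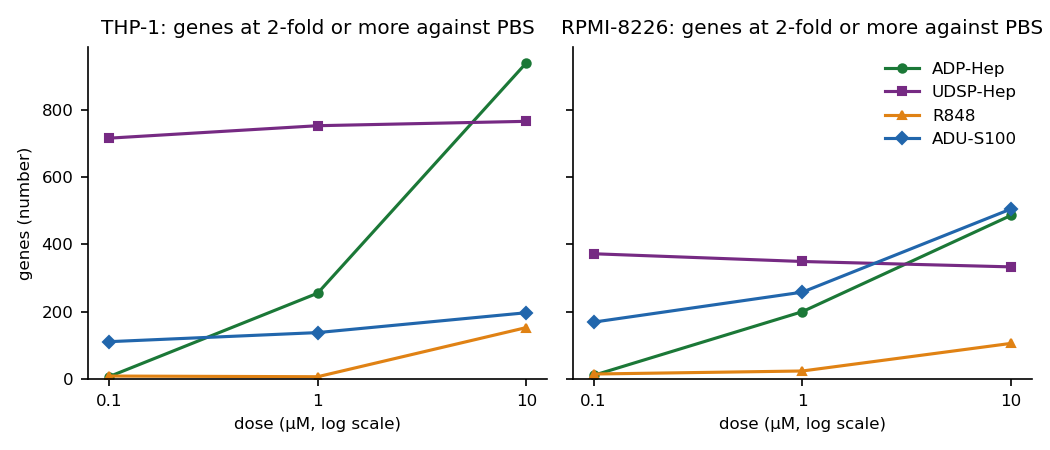
The lines join, for each agent, the number of genes at 2-fold or more against the PBS library of the same cell line at each dose (log scale). UDSP-Hep lies at 715 to 765 genes in THP-1 at all doses, and ADP-Hep runs from 7 to 939.

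In THP-1 cells, UDSP-Hep raised a broad inflammatory set averaged over its doses. TNFAIP3, which encodes the NF-kB inhibitor A20, rose 27.9-fold (log2 4.80 ± 0.71, adjusted p = 0.014) from 16.3 CPM in PBS to 358, 476 and 546 CPM at rising dose. The adhesion molecule gene ICAM1 rose 41.9-fold (5.39 ± 0.77, adjusted p = 0.013), the ubiquitin ligase gene BIRC3 39.7-fold (5.31 ± 0.72, adjusted p = 0.011) and the amino acid oxidase gene IL4I1 42.9-fold (5.42 ± 1.12, adjusted p = 0.04). Of the 31 NF-kB targets and feedback genes, 28 rose and none fell (29 adjusted over the list alone). Of 27 inflammatory cytokine and chemokine genes tested, 16 rose (18 adjusted over the list alone), among them CCL4 (log2 6.98 ± 0.66), IL1B (4.58 ± 0.44) and CXCL8 (4.38 ± 0.59). VCAM1, another adhesion molecule gene, had no count in PBS and reached 26.4 CPM at 10 µM, at least 346-fold higher. Type I interferon-stimulated genes rose in 22 of 41 cases (39 adjusted over the list alone), with the chemokine genes CXCL10 at log2 8.36 ± 1.63 and CXCL11 at 5.76 ± 0.84. IFIT1, an RNA-binding antiviral gene, went from 4.22 to 140 CPM at 0.1 µM but did not pass (adjusted p = 0.098). List medians were log2 3.11 for NF-kB targets, 2.45 for cytokines and 2.65 for interferon-stimulated genes, and 2.63, 1.93 and 2.65 with members of 3 or fewer PBS counts held at the 3-count floor. All 3 lists passed camera (adjusted p = 8.9e-35, 6.3e-08 and 8.9e-35), and none did with an estimated correlation (adjusted p = 0.0524, 0.0524 and 0.13).

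HMOX1, SLC7A11 and FTH1 also rose with UDSP-Hep in THP-1. HMOX1, which encodes haem oxygenase 1, rose 21.4-fold (log2 4.42 ± 0.20, adjusted p = 2.5e-17), the cystine transporter gene SLC7A11 5.10-fold (2.35 ± 0.12) and the ferritin gene FTH1 5.07-fold (2.34 ± 0.20). In the list of NRF2 targets and metallothioneins 12 of 21 rose (16 adjusted over the list alone, camera adjusted p = 4.2e-15, adjusted p = 0.0524 with an estimated correlation). The receptor genes TLR7 and TLR8 rose 8.69-fold and 7.80-fold, and TIFA rose 2.62-fold (log2 1.39 ± 0.14), among 13 receptor and signalling genes that rose and 2 that fell out of 26 (14 and 3 adjusted over the list alone). Immediate early and AP-1 genes rose in 15 of 28 cases and fell in 2 (17 and 2 adjusted over the list alone), with BTG2, a growth-restraining gene, at log2 3.70 ± 0.47 and the transcription factor gene EGR2 at 3.34 ± 0.82. In the list of feedback inhibitors of cytokine and Toll-like receptor signalling 9 of 19 members rose and 4 fell (10 and 5 adjusted over the list alone). Its members CD274, which encodes PD-L1, and PDE4B stood at log2 3.36 ± 0.78 and 3.19 ± 0.39. Membership was assigned, and whether these genes act as such inhibitors was not tested. Of the p53 and apoptosis genes 10 of 24 rose (11 adjusted over the list alone), with PHLDA3 at log2 1.73 ± 0.33, and of the MHC class I presentation genes 8 of 21 rose and 1 fell (9 and 1 adjusted over the list alone), with the peptide transporter gene TAP1 at 2.17 ± 0.40. The camera calls of these 5 lists (adjusted p = 0.0017, 1e-05, 0.014, 1.4e-05 and 1.4e-05) were lost with an estimated correlation (adjusted p = 0.146, 0.13, 0.167, 0.0671 and 0.167).

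The remaining lists went in both directions in THP-1 with UDSP-Hep or had few members tested. Sterol genes fell in 8 and rose in 2 of 25 cases (9 and 2 adjusted over the list alone), with the cholesterol exporter gene ABCG1 at log2 -1.03 ± 0.33 and ABCA1 at 0.65 ± 0.08 (camera adjusted p = 0.022, adjusted p = 0.171 with an estimated correlation). Unfolded protein and integrated stress genes rose in 4 and fell in 2 of 23 cases (4 and 2 adjusted over the list alone), with the serine synthesis gene PSAT1 at -1.40 ± 0.07, and their median of -0.03 and mean of 0.04 differed in sign (camera adjusted p = 0.37). Cell cycle genes rose in 6 and fell in 1 of 30 cases (6 and 1 adjusted over the list alone), and glycolysis and hypoxia genes in 5 and 5 of 27 (6 and 7 adjusted over the list alone), with neither list called (adjusted p = 0.37 and 0.93). For glycolysis the median was -0.03 and the mean 0.13, and the growth factor gene VEGFA stood at log2 1.53 ± 0.17. Monocyte markers rose in 6 and fell in 2 of 25 cases (6 and 2 adjusted over the list alone, adjusted p = 0.097), with the oxidase gene CYBB at 1.57 ± 0.21 and the transcription factor gene SPI1 at 1.20 ± 0.08. B and plasma cell markers rose in 4 and fell in 1 of 13 cases (4 and 1 adjusted over the list alone, adjusted p = 0.095; median log2 1.36, or 1.16 at the 3-count floor), with SLAMF7 at 3.66 ± 0.58 and PRDM1 at 2.47 ± 0.13. T and NK markers rose in 3 of 7 cases (3 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.136 with an estimated correlation), with the interleukin 7 receptor gene IL7R going from 9.79 to 111, 173 and 197 CPM. No mitochondrially encoded transcript of the 13 listed had a count in any library, so that list gave no test.

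Outside the lists, the largest rises with UDSP-Hep in THP-1 included IGFBP3 (log2 6.87 ± 1.05), the collagenase gene MMP1 (6.61 ± 0.71, from 0.15 to 25.0 CPM at 10 µM), the hyaluronan-binding protein gene TNFAIP6 (5.37 ± 0.56) and the cytokine gene IL33 (4.95 ± 0.74). SERPINB2, which encodes a plasminogen activator inhibitor, fell by 3.52 on the log2 scale (± 0.17) and the mTOR inhibitor gene DEPTOR by 2.65 (± 0.18). With edgeR, 2071 genes rose and 1743 fell after Benjamini-Hochberg adjustment, 3814 in total. The count was 2467 without the 0.1 µM library and 2448 without the 10 µM library, and 18 when doses entered as repeats of an agent. Along the UDSP-Hep doses 81 genes rose and 13 fell, among them ZBTB7C (log2 2.06 ± 0.42 per 10-fold dose) and the ectonucleotidase gene NT5E (0.68 ± 0.11), and the total of 94 was 0 without the 0.1 µM library and 4 without the 10 µM library. No list had more than 2 members rising along these doses, and no list passed with an estimated correlation (lowest adjusted p = 0.471).

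ADP-Hep raised many of these genes in THP-1 in a graded way. TNFAIP3 went from 16.3 CPM in PBS to 25.5, 186 and 518 CPM, and HMOX1 from 3.15 to 3.46, 15.7 and 67.5 CPM. Per 10-fold dose ICAM1 rose 6.29-fold (log2 2.65 ± 0.38, adjusted p = 0.014), BIRC3 5.47-fold (2.45 ± 0.35), IL1B 5.36-fold (2.42 ± 0.22), CCL4 20.2-fold (4.34 ± 0.33) and HMOX1 4.41-fold (2.14 ± 0.10, adjusted p = 9e-17). NF-kB targets rose in 27 of 31 cases (31 adjusted over the list alone), cytokines in 18 of 27 (18) and interferon-stimulated genes in 14 of 41 (36). NRF2 targets and metallothioneins rose in 14 of 21 (14), and none of these lists had a member that fell. Their camera calls held with an estimated correlation (adjusted p = 0.00172, 0.0316, 0.0481 and 0.0316). CXCL11 rose 6.26-fold per 10-fold dose (2.65 ± 0.38), while CXCL10, at 2.41, 31.3 and 104 CPM, did not pass (adjusted p = 0.057). TLR7 rose by log2 1.54 ± 0.21 and TIFA by 0.73 ± 0.08 per 10-fold dose. Outside the lists MMP1 (3.38 ± 0.32), TNFAIP6 (2.90 ± 0.29), the maturation marker gene LAMP3 (2.72 ± 0.24) and the gelatinase gene MMP9 (2.65 ± 0.26) rose, SERPINB2 fell by 2.27 (± 0.13), and DEPTOR by 1.62 (± 0.13). In all 2037 genes rose and 1476 fell along dose (edgeR, Benjamini-Hochberg), 3513 in total, against 1191 without the 0.1 µM library and 889 without the 10 µM library. Averaged over doses against PBS 825 rose and 565 fell, and 0 passed when doses entered as repeats. Of the NF-kB targets 9 rose in that contrast (26 adjusted over the list alone; adjusted p = 0.0907 with an estimated correlation).

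R848 changed THP-1 transcripts mainly at 10 µM. CXCL10 stood at 0.25 CPM in PBS and 0.78, 0.93 and 58.2 CPM at rising dose, and IFIT1 at 4.22 CPM in PBS and 88.5 CPM at 10 µM. Along dose the chemokine genes CCL4 (log2 4.53 ± 0.44) and CCL8 (4.23 ± 0.72), CXCL11 (4.29 ± 0.56), the matrix gene TNFAIP6 (2.39 ± 0.34) and LAMP3 (2.15 ± 0.25) rose, as did the costimulatory receptor gene CD40 (1.21 ± 0.10) and the RNase gene ZC3H12A (1.23 ± 0.12). Of 177 genes that rose and 16 that fell (edgeR, Benjamini-Hochberg), 162 of the rising ones also rose along the ADP-Hep doses. If calls were independent over all genes tested, 18.8 would be shared. Both slopes come from the same fit and share each gene's error, so calls can coincide more often than that without a shared response. NF-kB targets rose in 3 of 31 cases (22 adjusted over the list alone), cytokines in 4 of 27 (13), interferon-stimulated genes in 2 of 41 (6) and immediate early genes in 5 of 28 with 1 falling (14 and 1). Camera called these lists also with an estimated correlation (adjusted p = 0.0121, 0.0121, 0.0272 and 0.0295). Averaged over the doses only 3 genes differed from PBS, which were named after their values were seen: CD40 (log2 1.09), ZC3H12A (1.18) and the cytokine gene TNFSF15 (2.32), each at adjusted p = 0.0341, beside 795 genes at an unadjusted p under 0.05. That count was 0 without the 0.1 µM library, 31 without the 1 µM library and 0 without the 10 µM library, and the slope count was 0 without the 10 µM library.

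ADU-S100 raised interferon-stimulated genes in THP-1 at 10 µM. IFIT2 went from 7.83 CPM in PBS to 638 CPM and IFIT1 from 4.22 to 178 CPM at 10 µM, against 7.42 and 3.33 CPM at 0.1 µM. Neither passed along dose (adjusted p = 0.67 and 0.88), in a test that takes departure from a straight line as error. Along dose the list passed as a group, with median log2 1.16 per 10-fold dose (camera adjusted p = 2.2e-123, adjusted p = 0.0156 with an estimated correlation), with 1 of 41 members called (33 adjusted over the list alone). CCL4 (6.03 ± 1.03), TNFSF15 (1.69 ± 0.21), the stress transcription factor gene ATF3 (1.06 ± 0.16) and DHX58 (0.92 ± 0.17), which encodes the RNA sensor LGP2, rose along dose, among 31 genes that rose and 0 that fell (730 unadjusted). That count was 66, 67 and 2 without the 0.1, 1 and 10 µM libraries. Of the 31, 22 also rose along ADP-Hep doses, against 3.29 if calls were independent, which calls from the same fit are not. NF-kB targets gave no call along dose (0 of 31, median 0.02). The transcript of IFNB1, which encodes interferon beta, had 0 counts in PBS and 5.41 CPM at 10 µM (230 counts, 95% interval 4.73 to 6.16), and was the 1 tested member of the 12 interferon genes.

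**Figure D3:**
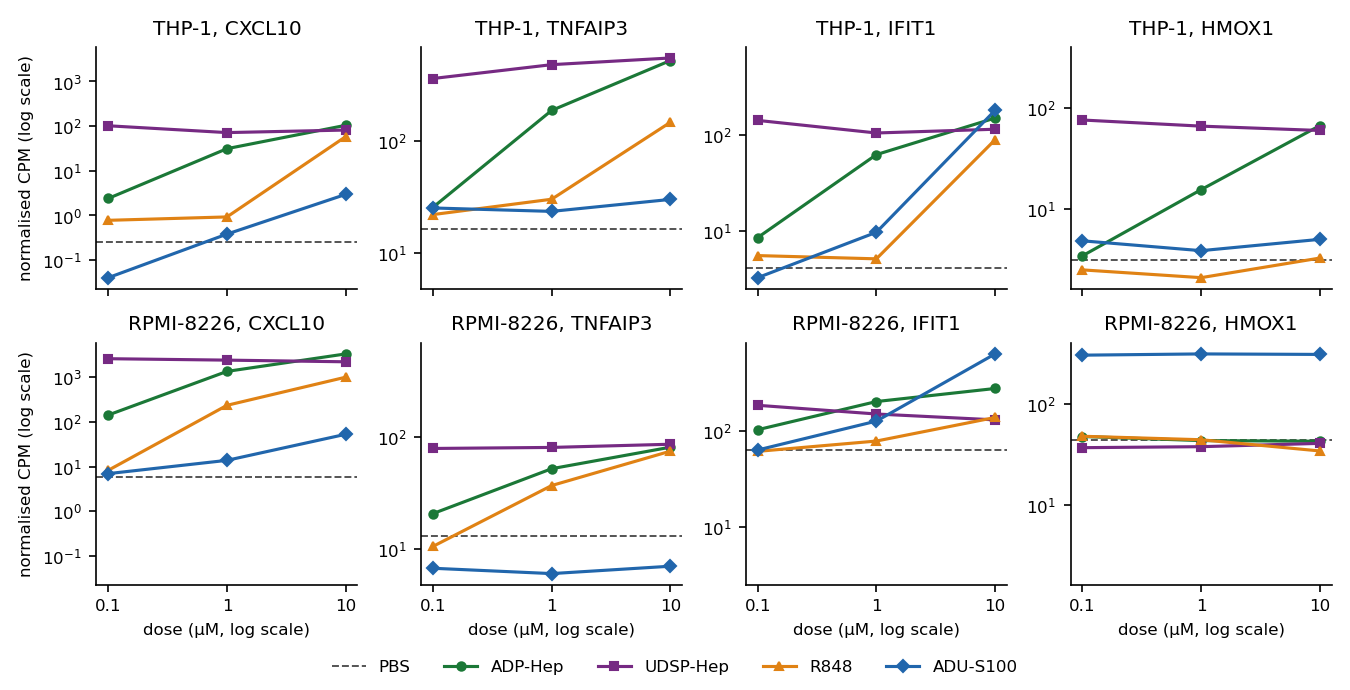
Points give the normalised CPM (log scale) of CXCL10, TNFAIP3, IFIT1 and HMOX1 in each library by dose (log scale), and the dashed line the PBS library of that line. In THP-1 HMOX1 reached 76.8 CPM at 0.1 µM UDSP-Hep and 67.5 CPM at 10 µM ADP-Hep from 3.15 CPM in PBS, and in RPMI-8226 it lay at 308 to 317 CPM with ADU-S100 from 44.8 CPM.

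Against PBS, ADU-S100 libraries of THP-1 differed in other genes already at 0.1 µM. EMP1, an epithelial membrane protein gene, stood at 1.12 CPM in PBS and 16.6, 12.3 and 16.1 CPM at rising dose (log2 3.74 ± 0.35). SLC7A11 (1.30 ± 0.11) and EGR3 (1.83 ± 0.40) were higher, the heat shock gene HSPA1B was lower by -2.25 ± 0.13, and the sterol gene MSMO1 lower by -0.86 ± 0.08. In edgeR 521 genes were higher and 597 lower. The interferon-stimulated list had 0 of 41 called, and the AP-1 list 6 higher and 1 lower of 28 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0005, adjusted p = 0.309 with an estimated correlation). Both lines' ADU-S100 libraries carry a different column prefix from every other library, PBS included, so agent and batch cannot be told apart in these counts, while the comparison along dose lies within 1 prefix.

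In RPMI-8226 cells UDSP-Hep raised the chemokine genes CXCL10 and CXCL9 and the antigen presentation genes CIITA and HLA-DRA. CXCL10 rose 417-fold (log2 8.71 ± 1.35, adjusted p = 0.021), from 5.82 CPM in PBS to 2626, 2440 and 2239 CPM, and CXCL9 rose 71.4-fold (6.16 ± 1.08). CIITA, the master regulator of MHC class II genes, rose 22.8-fold (4.51 ± 0.48), and the MHC class II gene HLA-DRA went from 1.58 to 7.72 CPM at 10 µM. NF-kB targets rose in 28 of 30 cases and fell in 1 (28 and 1 adjusted over the list alone), led by IL4I1 (16.7-fold, 4.06 ± 0.41), RELB (16.6-fold, 4.05 ± 0.46) and BIRC3 (13.4-fold, 3.74 ± 0.34). This list held with an estimated correlation (adjusted p = 0.026), with a median log2 of 2.23, or 2.09 with low PBS members at the floor. Interferon-stimulated genes rose in 28 of 42 cases (34 adjusted over the list alone), with the guanylate-binding protein genes GBP4 (3.37 ± 0.29) and GBP1 (2.92 ± 0.26), and MHC class I genes rose in 14 and fell in 1 of 21 (15 and 1), with TAP1 (1.27 ± 0.18) and HLA-F (1.17 ± 0.27). Cytokines and chemokines rose in 7 of 20 cases (11 adjusted over the list alone). Camera called these 3 lists (adjusted p = 2.7e-35, 5.2e-10 and 0.00016), but not with an estimated correlation (adjusted p = 0.124, 0.129 and 0.129). NRF2 targets and metallothioneins rose in 2 and fell in 1 of 20 cases (2 and 2 adjusted over the list alone, camera adjusted p = 0.61). The unfolded protein list fell in 9 and rose in 3 of 23 cases (11 and 3; camera adjusted p = 9.1e-05, adjusted p = 0.129 with an estimated correlation). B and plasma cell markers rose in 4 and fell in 5 of 20 cases (5 and 5 adjusted over the list alone, camera adjusted p = 0.515, median -0.02). Among them MS4A1, which encodes CD20, rose (1.41 ± 0.19), while BLK (-0.88 ± 0.08), the BCMA gene TNFRSF17 (-0.86 ± 0.08) and the syndecan gene SDC1 (-0.80 ± 0.06) fell.

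Outside the lists in RPMI-8226, the cytokine gene IL32 (log2 5.69 ± 0.91), WNT10A (4.81 ± 0.42) and the complement gene C3 (4.71 ± 0.57) rose with UDSP-Hep, and EFR3B fell by 2.77 (± 0.34). The syndecan gene SDC4 had no count in PBS and 2.02 CPM at 10 µM, at least 27.3-fold higher. In all 1439 genes rose and 1287 fell against PBS, 2726 in total, and 1562 passed without the 0.1 µM library, 1587 without the 10 µM library and 221 with doses as repeats. Along the UDSP-Hep doses edgeR called 0 genes, with 794 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The largest changes were APOBEC3A at -0.61 ± 0.19 (adjusted p = 1) and CDH3 at -0.53 ± 0.14 (adjusted p = 0.52), and the interferon-stimulated list had a median of -0.13 (camera adjusted p = 1.3e-20, adjusted p = 0.423 with an estimated correlation).

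ADP-Hep gave a graded response in RPMI-8226 as well. CXCL10 went from 5.82 CPM to 144, 1365 and 3360 CPM, and RELB from 2.66 to 10.5, 37.1 and 48.1 CPM. Per 10-fold dose CIITA rose by log2 1.88 ± 0.23, HLA-DRA by 1.62 ± 0.15, the cytidine deaminase gene APOBEC3A by 2.78 ± 0.19, the transcription factor gene STAT4 by 1.58 ± 0.13 and IL4I1 by 1.59 ± 0.20. TNFRSF17 fell by 0.72 (± 0.05), SDC1 by 0.56 (± 0.04) and the oncogene MYCN by 1.57 (± 0.19). Interferon-stimulated genes rose in 31 of 42 cases (38 adjusted over the list alone; adjusted p = 0.0841 with an estimated correlation), with GBP4 at 1.54 ± 0.14. NF-kB targets rose in 24 of 30 (27 adjusted over the list alone; adjusted p = 0.0255 with an estimated correlation), and MHC class I genes in 14 of 21 (16; adjusted p = 0.0911 with an estimated correlation). In all 1157 genes rose and 827 fell along dose, 1984 in total, against 496 without the 0.1 µM library and 805 without the 10 µM library. Against PBS 809 rose and 549 fell, and 0 passed when doses entered as repeats.

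In RPMI-8226, R848 moved inflammatory genes at 1 and 10 µM. CXCL10 stood at 8.34, 237 and 1012 CPM, and CCL4, with no count in PBS, at 25.3 CPM at 10 µM, at least 342-fold higher. Per 10-fold dose NFKBIZ, an NF-kB cofactor gene, rose 4.42-fold (log2 2.14 ± 0.19) and the activation marker gene CD83 3.22-fold (1.69 ± 0.12). TLR7 rose by 1.01 ± 0.12, the integrin gene ITGB8 by 2.31 ± 0.29, CIITA by 1.59 ± 0.23 and MS4A1 by 0.80 ± 0.10. NF-kB targets rose in 21 of 30 cases (24 adjusted over the list alone), cytokines in 4 of 20 (11) and feedback inhibitors in 4 of 17 (5), and these calls held with an estimated correlation (adjusted p = 0.0189, 0.0222 and 0.0427). Interferon-stimulated genes rose in 8 of 42 cases (19; adjusted p = 0.154 with an estimated correlation). Of 428 genes that rose and 115 that fell along dose, 308 of the rising ones also rose along ADP-Hep doses. If calls were independent, which calls from the same fit are not, 28.2 would be shared. The total of 543 was 65 without the 0.1 µM library and 42 without the 10 µM library. Averaged against PBS 65 genes rose, with WNT10A (2.80 ± 0.42) and the repressor gene BCL6 (2.52 ± 0.54), and 8 fell, and this total of 73 was 28, 119 and 26 without the 0.1, 1 and 10 µM libraries.

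ADU-S100 raised interferon-stimulated genes in RPMI-8226 in steps. IFIT2 rose 4.65-fold per 10-fold dose (log2 2.22 ± 0.07, adjusted p = 2.8e-27), from 11.9 CPM in PBS to 11.9, 48.1 and 252 CPM, and OASL 3.34-fold (1.74 ± 0.08), with IFIT3 (1.84 ± 0.22) and RSAD2 (1.67 ± 0.23). Of the list 32 of 42 rose (35 adjusted over the list alone, camera adjusted p = 6.7e-80, adjusted p = 0.0519 with an estimated correlation). The nuclear receptor gene NR4A3 (1.77 ± 0.19), the death ligand gene TNFSF10 (1.43 ± 0.11) and APOBEC3A (2.14 ± 0.19) rose, and the plasma cell factor gene IRF4 fell by 0.38 (± 0.04). NF-kB targets rose in 4 of 30 cases (5 adjusted over the list alone with 1 falling; adjusted p = 0.393 with an estimated correlation). Of 923 genes that rose and 496 that fell, 1419 in total, 484 passed without the 0.1 µM library and 32 without the 10 µM library. IFNB1 had 0.0493 CPM in PBS (2 counts) and 1.15 CPM at 10 µM (46 counts, 0.841 to 1.53), and IFNG, the other of the interferon genes tested, had an adjusted p of 0.97. Against PBS, HMOX1 was 6.97-fold higher (2.80 ± 0.09), the serine synthesis gene PHGDH 4.92-fold (2.30 ± 0.11) and the unfolded protein factor gene XBP1 2.15-fold, and the mitotic kinase gene PLK1 was lower by -0.94 ± 0.06. Unfolded protein genes were higher in 13 and lower in 3 of 23 cases (14 and 3 adjusted over the list alone), cell cycle genes lower in 17 and higher in 2 of 30 (17 and 2), sterol genes lower in 17 and higher in 4 of 25 (17 and 4) and glycolysis genes lower in 14 and higher in 3 of 28 (15 and 3), and none of these 4 lists held with an estimated correlation (adjusted p = 0.107, 0.107, 0.126 and 0.107). In all 1566 genes were higher and 2205 lower than in PBS, 3771 in total, against 2457 without the 0.1 µM library, 2465 without the 10 µM library and 1466 with doses as repeats, and here too agent and column prefix cannot be told apart.

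**Figure D4:**
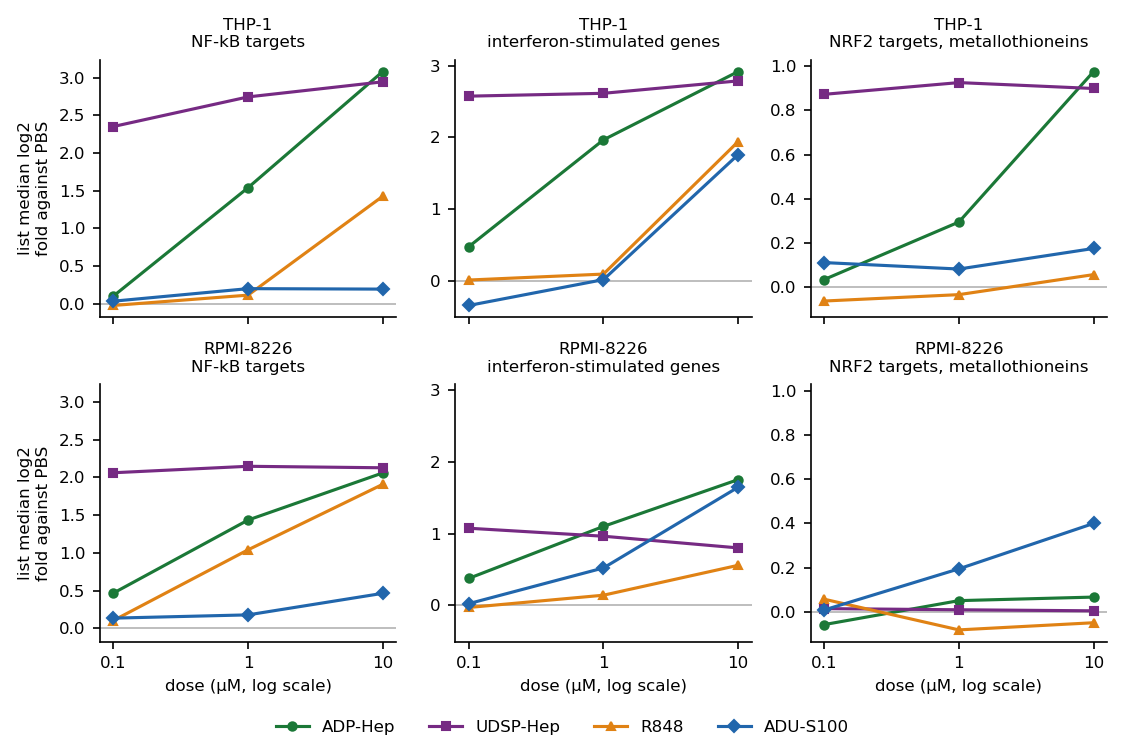
Each point is the median log2 fold against PBS of a gene list in 1 library, by dose (log scale), for NF-kB targets, interferon-stimulated genes and NRF2 targets with metallothioneins in each line. Interferon-stimulated genes stand at 2.58, 2.62 and 2.79 with UDSP-Hep and at 0.48, 1.97 and 2.92 with ADP-Hep in THP-1, and at -0.34, 0.02 and 1.76 with ADU-S100.

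The ALPK1 agonists were compared at matched doses, with the contrasts at 0.1 and 10 µM chosen after the values were seen. In THP-1 at 0.1 µM, UDSP-Hep gave higher HMOX1 than ADP-Hep by log2 4.45 (95% fitted interval 4.07 to 4.82), ICAM1 by 4.71 (2.87 to 6.56), BIRC3 by 4.10 (2.40 to 5.79) and IL1B by 4.03 (3.03 to 5.03). CXCL10 differed by 4.66 (1.80 to 7.51) and did not pass (adjusted p = 0.061). Of the NF-kB targets 26 of 31 were higher with UDSP-Hep at this dose (30 adjusted over the list alone), and 1710 genes were higher and 1248 lower. At 10 µM only 18 were higher and 9 lower, and 0 NF-kB targets and 0 interferon-stimulated genes were called. There the differences were -0.18 for HMOX1 (-0.50 to 0.14), -0.32 for ICAM1 (-1.89 to 1.24), -0.14 for TNFAIP3 (-1.71 to 1.43) and -0.75 for CXCL10 (-3.17 to 1.66), so a difference of over 3-fold in the last 3 is not excluded. Averaged over doses HMOX1 differed by 2.13 (1.91 to 2.35), TRAF1 by 1.80 ± 0.21, CCL4 by 3.81 ± 0.34 and MMP1 by 3.02 ± 0.34. NF-kB targets were higher in 13 of 31 cases (26 adjusted over the list alone, camera adjusted p = 0.00494 with an estimated correlation). Cytokines were higher in 9 of 27 (13, 0.0418), NRF2 targets and metallothioneins in 13 of 21 (14, 0.0244), and interferon-stimulated genes in 2 of 41 (6, 0.0751). In edgeR 933 genes were higher and 501 lower, 1434 in total, and the slope with UDSP-Hep minus that with ADP-Hep was positive in 749 genes and negative in 1062. The mean count was 796 and 817 without the 0.1 and 10 µM ADP-Hep libraries, 558, 877 and 547 without the UDSP-Hep libraries at rising dose, and 0 in a fit of the 6 libraries with dose as a block. The slope count of 1811 was 739, 716, 295 and 312 without the 0.1 or 10 µM ADP-Hep and the 0.1 or 10 µM UDSP-Hep library.

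In RPMI-8226 the order of the compounds turned with dose for some genes. At 0.1 µM UDSP-Hep gave higher NFKBIA by log2 2.39 (2.05 to 2.72), APOBEC3A by 2.40 (1.66 to 3.14), HLA-DRA by 2.06 (1.47 to 2.65) and OASL by 0.81 (0.47 to 1.14). At 10 µM it gave lower APOBEC3A by -4.39 (-5.09 to -3.70), OASL by -1.66 (-1.99 to -1.33), TNFSF10 by -1.47 (-1.87 to -1.07), HLA-DRA by -1.22 (-1.76 to -0.67) and the NAD hydrolase gene CD38 by -0.76 (-0.92 to -0.60), while NFKBIA differed by -0.01 (-0.33 to 0.30). NF-kB targets were higher in 24 and lower in 1 of 30 cases at 0.1 µM (25 and 1 adjusted over the list alone; adjusted p = 0.0202 with an estimated correlation) and lower in 2 at 10 µM (2; 0.416). Interferon-stimulated genes were higher in 13 of 42 at 0.1 µM (24; 0.0908) and lower in 17 at 10 µM (35; 0.11), with none in the other direction. Over all genes 808 were higher and 595 lower at 0.1 µM, and 152 higher and 309 lower at 10 µM. Averaged over doses 533 were higher and 475 lower, 1008 in total, with the prostaglandin receptor gene PTGER4 at 1.59 ± 0.19 and the protocadherin gene PCDH1 at -1.83 ± 0.19, and the slope difference was positive in 405 and negative in 644. The mean count was 264 without the 0.1 or the 10 µM ADP-Hep library, 236, 655 and 247 without the UDSP-Hep libraries at rising dose, and 0 with dose as a block of 6 libraries. The slope count of 1049 was 459 and 627 without the 0.1 and 10 µM ADP-Hep libraries and 203 and 249 without those of UDSP-Hep.

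Responses differed between the lines for named genes of each agent. With UDSP-Hep HMOX1 rose in THP-1 (log2 4.39) and not in RPMI-8226 (-0.20), a difference of 4.59 ± 0.19 (adjusted p = 9e-15), and SLC7A11 differed by 2.43 ± 0.17, FTH1 by 1.81 ± 0.23 and ICAM1 by 3.45 ± 0.61. CIITA differed the other way, by -4.69 ± 0.75, as did HLA-DRA by -1.69 ± 0.35, while the NF-kB feedback gene NFKBIA, at 0.38, did not pass (adjusted p = 0.84). With ADP-Hep against PBS, HMOX1 differed by 2.26 ± 0.20 (adjusted p = 1.4e-07) and CIITA by -3.24 ± 0.75 (adjusted p = 0.046). Against PBS with ADU-S100, HMOX1 differed by -2.25 ± 0.21, PHGDH by -2.27 ± 0.19 and EMP1 by 3.49 ± 0.59. For these values, and for the number of genes with ADU-S100 against PBS given next, agent and column prefix cannot be told apart. In the joint edgeR fit 1955 of 21878 genes differed between the lines in their change with UDSP-Hep, 414 with ADP-Hep and 1475 with ADU-S100, and along dose 1212 with ADP-Hep, 80 with R848 and 88 with ADU-S100. Only 2 differed along the UDSP-Hep doses, named after their values were seen: the desmosome gene PKP2 (-0.99 ± 0.17, adjusted p = 0.039) and the syndecan gene SDC2 (1.30 ± 0.20, adjusted p = 0.012). The 2 in the change with R848 were SDC4 (adjusted p = 0.01), which had no count in PBS of RPMI-8226, and the matrix gene EMILIN2 (4.20 ± 0.54, adjusted p = 8e-04). As lists, NRF2 targets and metallothioneins differed by a median of 0.91 with UDSP-Hep (camera adjusted p = 1.8e-15, adjusted p = 0.0521 with an estimated correlation). The interferon-stimulated list differed by 1.56 (camera adjusted p = 0.27 with an estimated correlation). NF-kB targets differed by -0.35 with R848 against PBS, the list difference that held with an estimated correlation (adjusted p = 0.0163).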

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

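The tests on the ADU-S100 libraries and on the labels of the 0.1 µM libraries in this part were chosen only after the results were seen, while the counts over other splits of the libraries were planned. Responses differed between THP-1 and RPMI-8226 in a test of the difference itself, in the joint edgeR fit of the 26 libraries, for these 8 counts of genes. Against PBS, 1955 genes differed with UDSP-Hep, 909 with the more positive change in THP-1 and 1046 in RPMI-8226, a balance that turned to 1044 and 945 with relative log expression scaling, 1293 and 1087 with the CPM filter and 1146 and 993 with DESeq2. With ADP-Hep it was 414 genes (216 and 198; 649 with DESeq2, 643 with the CPM filter and 209 with limma-voom). With ADU-S100 it was 1475 (816 and 659), where agent and column prefix cannot be told apart. With R848 only 2 genes differed (1 and 1), beside 1070 at an unadjusted p under 0.05 (15 with DESeq2, 0 with limma-voom). Along dose 1212 genes differed with ADP-Hep (606 and 606, but 750 and 521 with relative log expression scaling, 926 and 653 with the CPM filter and 862 and 585 with DESeq2), 80 with R848 (27 and 53; 258 with DESeq2, 145 with the CPM filter and 40 with limma-voom) and 88 with ADU-S100 (16 and 72; 347 with DESeq2 and 143 with the CPM filter). Along the UDSP-Hep doses 2 genes differed (1 and 1), beside 1273 unadjusted (30 with DESeq2, 6 with the CPM filter, 4 with relative log expression scaling, 0 with limma-voom).

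ADU-S100 libraries stood apart from PBS from 0.1 µM on in both lines. Outside the interferon-stimulated list, 1118 genes in THP-1 and 3749 in RPMI-8226 were called against PBS, of which 8 and 756 were also called along dose, and the median ratio of their change at 0.1 µM to that at 10 µM was 0.978 and 0.812. For the genes not called along dose, a batch difference of the column prefix and a compound effect already full at 0.1 µM cannot be told apart, since no PBS library carries the prefix of the ADU-S100 libraries. The 8 and 756 genes also called along dose changed within the prefix, which neither of these alone would give. Interferon-stimulated genes rose within that prefix by a median log2 of 2.11 in THP-1 and 1.48 in RPMI-8226 between 0.1 and 10 µM, which argues against batch for this list, and they lay at -0.34 and 0.0236 against PBS at 0.1 µM, which argues against an interferon response complete at that dose. An action of ADU-S100 on these genes that sets in above 0.1 µM remains a hypothesis.

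UDSP-Hep was near its plateau at 0.1 µM while ADP-Hep at 0.1 µM lay near PBS, which a difference in potency between the compounds, still a hypothesis, or a wrong label may give. If the ADP-Hep 0.1 µM library were an untreated one, genes that rise along the R848 doses, which share no library with it, should stay at PBS. In RPMI-8226 their median log2 was 0.120 (347 of 428 genes above PBS, against at most 0.0214 in 10000 random lists). CXCL10 stood there at 144 CPM against 5.82 in PBS. Random lists hold unrelated genes, so they do not show how far genes that rise together shift between untreated libraries. The RPMI-8226 values therefore speak against an untreated library but do not settle it. In THP-1 the median was 0.0711 (116 of 177, at most 0.0524), above the random lists but below the bound of 0.1, itself set after the data were seen. In that THP-1 library the interferon-stimulated median of 0.48 and CXCL10 at 2.41 CPM, against 0.25 in PBS, speak against an untreated library, but only the libraries of 0.1 and 1 µM R848, with medians of 0.01 and 0.09 and CXCL10 at 0.78 and 0.93 CPM, show how far single libraries of that prefix vary, too few to settle it. A 10 µM library under the UDSP-Hep 0.1 µM label should leave few genes changing along the UDSP-Hep doses. Separate libraries of the same dose can also differ, however, by an amount not measured without replicates. THP-1 had 94 such genes with edgeR, 104 with DESeq2, 124 with limma-voom and 67 without the 1 µM library, above a bound of 50 set after the data were seen. The joint fit had 49, a linear dose scale 0 (1089 unadjusted) and the fits without the 0.1 or 10 µM library 0 and 4. RPMI-8226 had 0 with edgeR (794 unadjusted, 1 with DESeq2, 0 with limma-voom). These counts cannot decide on the UDSP-Hep 0.1 µM label, which stays open in both lines.

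Between UDSP-Hep and ADP-Hep averaged over doses, 1434 genes differed in THP-1 and 2 of the 10 splits of the 6 libraries gave as many, with 1906 in the split that exchanges the 10 µM libraries of the compounds. In RPMI-8226 1008 genes differed, 1 of the 10 splits gave as many, and the highest other split gave 585. In both lines 10 splits are too few for a share under 0.05. For the receptor list limma-voom called 23 genes between the lines. Of 100 splits within the pairs of matched condition 1, the real one, gave as many, with 20 in the highest other. Most genes differed between these lines, 18085 of 21878 tested in edgeR, so the real split would be likely to lead for most lists. The splits therefore say nothing particular about the receptor list.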

How the results depend on the processing

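The fits of counts halved and rounded, of the S0401 libraries only (for agents against PBS and UDSP-Hep against ADP-Hep) and with quadratic terms for R848 and ADU-S100 were chosen after the data were seen, and the others were planned. Over all alternatives 196 of 298 counts of genes stayed within 1.5 times the reported count and 102 did not. No gene or list followed through them changed direction, but a change was unlikely by construction. Most genes followed were picked for the same direction at all doses or dose steps. Lists were only tested again on the same fit, with an estimated correlation or fry. The larger of the higher and lower calls changed sides in 10 of 247 comparisons with at least 20 calls. Apart from the line difference with UDSP-Hep given above, higher and lower calls became 1673 and 1746 for UDSP-Hep against PBS in THP-1 (joint fit, reported 2071 and 1743), 592 and 586 for ADU-S100 against PBS in THP-1 (CPM filter, 521 and 597), and 104 and 105 for the line difference with ADP-Hep (limma-voom, 216 and 198). In RPMI-8226 they became 228 and 246 for the ADP-Hep slope (linear dose, 1157 and 827), 94 and 127 for UDSP-Hep against PBS (agent means only, 1439 and 1287), and 127 and 137 or 124 and 140 for the UDSP-Hep minus ADP-Hep mean (without 0.1 or 10 µM ADP-Hep, 533 and 475). The genes followed were those with the largest changes outside the lists and the largest differences between UDSP-Hep and ADP-Hep. Their calls were kept in 2561 comparisons and lost in the same direction in 620. List members named against PBS or along dose, such as TNFAIP3 and HMOX1, were not followed, nor were genes compared at single doses or between the lines. Calls of gene lists were kept in 140 and lost in 200, of which 142 with an estimated correlation and 58 with fry. The 24 numbers of genes at 2-fold or more stayed within 1.5 times the reported number with a prior count of 0.5, and all 24 were higher with a floor of 1 CPM and lower with 20 CPM, each by over 1.5 times. Relative log expression scaling changed no call of the genes followed. Unless shown by a left-out library or by the construction of the fit, the cause was not tested. No analysis paired by replicate was possible because each condition had 1 library, so the groups compared share fewer than 2 replicate numbers. The pairs and blocks used in the text are matched doses or conditions. PBS was never left out, since no comparison with PBS remains without it. Depth limits what low genes can show: a change in a gene below 0.0613 to 0.0875 CPM, 3 counts, is not measured.

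Counts as reported are followed here by the lowest and highest when each library of the agents compared was left out. In THP-1, ADP-Hep against PBS gave 1390 (968 to 1622) and along dose 3513 (889 to 3846), UDSP-Hep 3814 (2448 to 3201) and 94 (0 to 67), R848 3 (0 to 31) and 193 (0 to 243), ADU-S100 1118 (771 to 986) and 31 (2 to 67), and UDSP-Hep minus ADP-Hep 1434 (547 to 1404) for the mean and 1811 (295 to 2116) for the slope. In RPMI-8226 the same order gave 1358 (1283 to 1389) and 1984 (496 to 2328), 2726 (1562 to 2279) and 0 (0 to 0), 73 (26 to 119) and 543 (42 to 584), 3771 (2457 to 3426) and 1419 (32 to 1383), and 1008 (236 to 1407) and 1049 (203 to 1325).

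With agent means only, where differences between doses count as error, THP-1 gave 0 for ADP-Hep (1392 at an unadjusted p under 0.05), 18 for UDSP-Hep, 0 for R848 (389 unadjusted), 117 for ADU-S100 and 0 for UDSP-Hep minus ADP-Hep (1594 unadjusted), and RPMI-8226 gave 0 (1373 unadjusted), 221, 0 (511 unadjusted), 1466 and 4. With dose as a block of 6 libraries the mean difference of UDSP-Hep and ADP-Hep gave 0 in THP-1 (1038 unadjusted) and 0 in RPMI-8226 (1170 unadjusted). On a linear dose scale the slopes gave 2081 for ADP-Hep, 0 for UDSP-Hep (1089 unadjusted) and 8 for R848 in THP-1, and 474 for ADP-Hep, 13 for R848 and 615 for ADU-S100 in RPMI-8226. The joint fit of 26 libraries gave, in THP-1, 0 for R848 against PBS (755 unadjusted) and slopes of 117 for R848 and 49 for UDSP-Hep. In RPMI-8226 it gave 839 for ADP-Hep and 31 for R848 against PBS, slopes of 723 for ADU-S100, 269 for R848 and 1 for UDSP-Hep, and 571 and 568 for the mean and slope of UDSP-Hep minus ADP-Hep. Quadratic terms gave 21 for R848 against PBS and slopes of 315 for R848 and 129 for ADU-S100 in THP-1, and 1 for the UDSP-Hep slope in RPMI-8226.

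Without a filter, THP-1 gave 36 for R848 against PBS and slopes of 354 for R848, 97 for ADU-S100 and 176 for UDSP-Hep, and RPMI-8226 gave 160 for R848 against PBS. R848 against PBS in THP-1 gave 0 in each of 4 other fits: at least 1 CPM in 3 libraries (615 unadjusted), the S0401 libraries only (858), counts halved (800) and limma-voom (809). DESeq2 gave a slope count of 50 for ADU-S100 in THP-1 and 1 for UDSP-Hep in RPMI-8226, and limma-voom gave 44 for R848 against PBS in RPMI-8226. For differences between the lines, DESeq2 gave 649 with ADP-Hep against PBS (reported 414) and 15 with R848 against PBS (2), and along dose 347 with ADU-S100 (88), 258 with R848 (80) and 30 with UDSP-Hep (2). The filter of at least 1 CPM in 3 libraries of each line gave 643 with ADP-Hep against PBS and slopes of 143 with ADU-S100, 145 with R848 and 6 with UDSP-Hep, and relative log expression 4 with the UDSP-Hep slope. Limma-voom gave 209 with ADP-Hep and 0 with R848 against PBS (1009 unadjusted), and along dose 40 with R848 and 0 with UDSP-Hep (1054 unadjusted). The line difference in slope has the least power of the simulated comparisons run, with 49 and 70% of changes of log2 0.5 and 1 recovered.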

Other observations

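The genes named in this part and the tests on IFNB1 were chosen only after the results were seen, and the test on even counts was chosen before. STING1, the receptor gene of ADU-S100, fell in THP-1 with the ALPK1 agonists. It stood at 139 CPM in PBS and at 73.6, 75.9 and 74.5 CPM at rising UDSP-Hep dose (log2 -0.90 ± 0.09, adjusted p = 2.3e-09), and it fell along the ADP-Hep doses through 123, 108 and 65.6 CPM (-0.45 ± 0.06 per 10-fold dose, adjusted p = 5.8e-07). With ADU-S100 itself STING1 did not pass (adjusted p = 0.69). The lactate exporter gene SLC16A3 rose (1.18 ± 0.09) and the hexokinase gene HK2 fell (-0.96 ± 0.11) with UDSP-Hep in THP-1. In RPMI-8226 the stress gene NDRG1 fell with UDSP-Hep (-1.66 ± 0.11) and along ADP-Hep dose (-0.77 ± 0.07), and PSAT1 fell with UDSP-Hep (-0.44) and was higher with ADU-S100 than with PBS (0.82 ± 0.07).

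Some heat shock genes, named from a larger set that was not tested as a group, were lower in the ADU-S100 libraries than in PBS. Other members are not given, so the share of the set that was lower is not shown here. DNAJB1, a cochaperone gene, stood at 184 CPM in PBS and 72.3, 69.2 and 64.3 CPM at rising dose in THP-1 (log2 -1.42 ± 0.07), and at 296 against 145, 155 and 175 CPM in RPMI-8226 (-0.91 ± 0.06). HSPH1 was lower by -0.89 in THP-1 and -0.46 in RPMI-8226, HSPA8 by -0.67 and -0.19, and BAG3 by -0.77 and -1.16. HSPB1 was lower in RPMI-8226 (-0.90 ± 0.08) and did not pass in THP-1 (adjusted p = 0.96). In RPMI-8226 the surface genes CD38 (1.32 ± 0.07, from 105 to 215, 252 and 333 CPM) and MRC1 (1.11 ± 0.10, from 39.6 to 71.3, 80.9 and 107 CPM) were higher with ADU-S100. The interferon-inducible gene IFI27 was lower there (-2.09 ± 0.07), at 137 CPM in PBS and 25.6, 28.7 and 44.6 CPM. The prefix of the ADU-S100 columns applies to each of these differences from PBS.

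A hypothesis for the interferon-stimulated genes that rose with ADP-Hep and UDSP-Hep was an IFNB1 transcript at 4 h at the level seen with 10 µM ADU-S100. In THP-1 the highest IFNB1 value of the 6 libraries was 0.155 CPM (6 counts, 95% interval 0.0568 to 0.337), against 5.41 CPM (4.73 to 6.16) with ADU-S100, which argues against it. In RPMI-8226 it was 0.331 CPM (13 counts, 0.176 to 0.567) against 1.15 CPM (0.841 to 1.53), and the 6 libraries together held 0.197 CPM (45 counts). The upper bound of these together, 0.297 CPM with counts halved, lay below 0.5 times the lower bound of ADU-S100, 0.728 CPM with counts halved. This argues against that level of IFNB1 at 4 h in RPMI-8226 as well, while lower levels and earlier times were not tested. A stricter bound set first, 0.2 times in place of 0.5, was not met in RPMI-8226.

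Among genes with 1 to 20 counts, 67.5 to 72.0% of the values were even in each library, and a candidate explanation is that both mates of a read pair were counted. In that case genes free of exon overlap should hold more even values than genes with overlap, where 1 mate can be lost as ambiguous. The difference was at least 6.70 percentage points in every library (70.4 to 75.1% against 60.9 to 66.2%), as this hypothesis requires. Counting intervals in the text would then be too narrow, since they take each count as 1 fragment, and the lower bounds on folds of VCAM1, CCL4 and SDC4 would be 0.5 times those given.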
